A study of Glycine soja with 14 samples.

How the data were processed

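Leaves of 3-week-old wild soybean seedlings were sampled before treatment (0 h) and at 6 later times up to 24 h in 50 mM sodium bicarbonate. Each time had 2 arrays, each from the pooled leaves of 3 plants, per the labels. Total RNA was extracted with TRIzol, labelled with biotin and hybridised to 1-colour Affymetrix soybean arrays, per the labels' protocols. Plants grew under 12 h of light and 12 h of dark, and the clock hours of sampling are not given in the sources used here.

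The deposited table holds 1 intensity per probe set and array on a linear scale, from 0.92 to 12812.33. From the deposited intensity values, the arrays have similar means and medians but not identical distributions, so they look scaled to one another and not quantile normalized. The normalization method of the authors, the software and the summary method are not given in the sources used here. The table has 61170 probe sets. Of these, 37593 are named for soybean, 15820 for Phytophthora sojae and 7530 for Heterodera glycines, a water mould and a nematode that infect soybean and are represented on the same array. The other 227 are control and ribosomal RNA probe sets and were left out of the tests.

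Each array was scaled to a common soybean median of 56.4, which shifted the median change at a time by at most 0.0588 log2, and values were taken as log2(value + 16). A log2 change on this scale understates the change of dim genes. The 23350 probe sets of the 2 other organisms gave the background, set for each array at their 95th percentile. Where a gene was not above background on any array of 1 group, its change is given as at least N-fold: the bright group's mean against the dim group's mean of, per array, the higher of the background and the gene's own signal.

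The limma package 3.58.1 in R 4.3.3 was used to fit 7 group means to all 14 arrays (lmFit, eBayes), with 7 residual degrees of freedom and 4.24 prior ones. Contrasts were each of the 6 later times against 0 h, the 5 steps between consecutive times and the F test over the 6 contrasts against 0 h. Tests were two-sided, with Benjamini-Hochberg adjustment per contrast and a threshold of 0.05. These tests, the alternatives, the rule for named genes and 9 of the gene lists were fixed before the data were examined. The fit was tried on simulated data with independent normal noise and 200 changed probe sets among 37593. The 200 were drawn only from probe sets with a mean above background, so recovery of dim ones is not covered. It recovered 0 to 4% of changes of log2 0.5, 52 to 66% of those of 1, 96 to 100% of those of 2 and 100% of those of 3. There were 5 to 8 false calls per time.

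Gene names came from the array's public annotation table, which is some years old. Of the soybean probe sets, 8677 had 1 gene symbol, 370 had several and 28546 had none. No identifier matched the reference gene table of Glycine soja given for this work, so neither newer names nor genome positions are given. The named probe sets covered 6029 genes, each represented by the probe set with the highest mean over all arrays, and 1003 of these had a name other than a LOC number. Genes were named by rule: at each time the 5 largest rises and the 5 largest falls past the test, above background in at least 1 group and with both treated arrays on the same side of both 0 h arrays. Up to 4 members of each list by the same filters, the member with the lowest p where none passed, the 10 genes with the lowest F test p and the clock genes at every time were also named. A further rule, the largest rises and falls among genes with a name other than a LOC number, was added after the annotation was seen.

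Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, in 204 list tests adjusted together. Of 35 lists, 9 were fixed as name patterns: WRKY, NAC, MYB and bZIP factors, heat shock, jasmonate, gibberellin and cytokinin, glutathione transferases and aquaporins. More patterns had been fixed, but they rely on gene descriptions, which the annotation lacks. In their place 26 lists were written from the symbols of the annotation, after it was seen and before any value per gene was seen. The clock list had 4 genes, under the minimum of 5, and was described without a list test. In a simulation a list of 20 genes shifted by log2 0.5 was called higher by camera, and 8 of 100 unchanged lists had an unadjusted p under 0.05.

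Alternatives were quantile normalization, median centring of log2 values, a filter on dim probe sets, log2(value + 1) and log2(value + 64). Another included the array's other probe sets, those of other organisms and the control and ribosomal RNA ones. Further ones were the replicate number as a block, only the groups compared, and eBayes with trend and robust settings. Stricter thresholds, other list settings and each array left out in turn were also used. Values without scaling, a fit without the 12 h arrays and a fit without the 0.5 h arrays were added after the data were seen.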

Results

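Transcript levels were measured in young leaves of wild soybean (Glycine soja, line G07256), the wild relative of cultivated soybean. Seedlings were moved into nutrient solution with 50 mM sodium bicarbonate, which makes the root medium alkaline and adds sodium. Leaves were taken at 0 h, without treatment, and at 0.5, 1, 3, 6, 12 and 24 h. Each time had 2 independent biological replicates, and each replicate was 1 array hybridised with RNA pooled from the leaves of 3 plants, 14 arrays in all. The summed intensity per array was 7413140 to 8230030. Between 24843 and 29013 of the 37593 soybean probe sets (66.1 to 77.2%) lay above background, and replicate arrays of a time correlated at 0.965 to 0.985 across probe sets. The arrays of 0 h, which serve every comparison against 0 h, were the least alike. The SD of the difference between them across probe sets was 0.439 log2, against 0.285 to 0.424 at the other times. With 2 arrays per time, the number of arrays limits the precision, and the median SE of a log2 change was 0.19. The SE pools the spread of a probe set over all times, so it may understate the error of changes against 0 h.

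The series set out to find genes of the alkaline-stress response in leaves, with attention to transcription factors and abscisic acid signalling. Untreated leaves were taken at 0 h only, so hours of treatment and time of day changed together at every later time, except that 24 h falls at the clock hour of 0 h. Changes below are log2 differences from 0 h ± SE with n = 2 arrays per time. Every named gene called changed had both treated arrays on the same side of both 0 h arrays. Adjusted p-values are limma's, over all soybean probe sets.

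Leaves changed most at 12 h. MYB134, a MYB transcription factor, FAD6.1, a plastid fatty acid desaturase, and MYB118 had among the lowest p-values of the whole course, and all 3 fell at 6 and 12 h. Over the course 11428 of 37593 probe sets differed by limma's F test, with adjusted p = 3.49e-08 for MYB134, 9.59e-07 for FAD6.1 and 1.45e-06 for MYB118. At any single time 11223 probe sets differed from 0 h, and 10305 of them did so at 6 or 12 h.

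**Figure D1:**
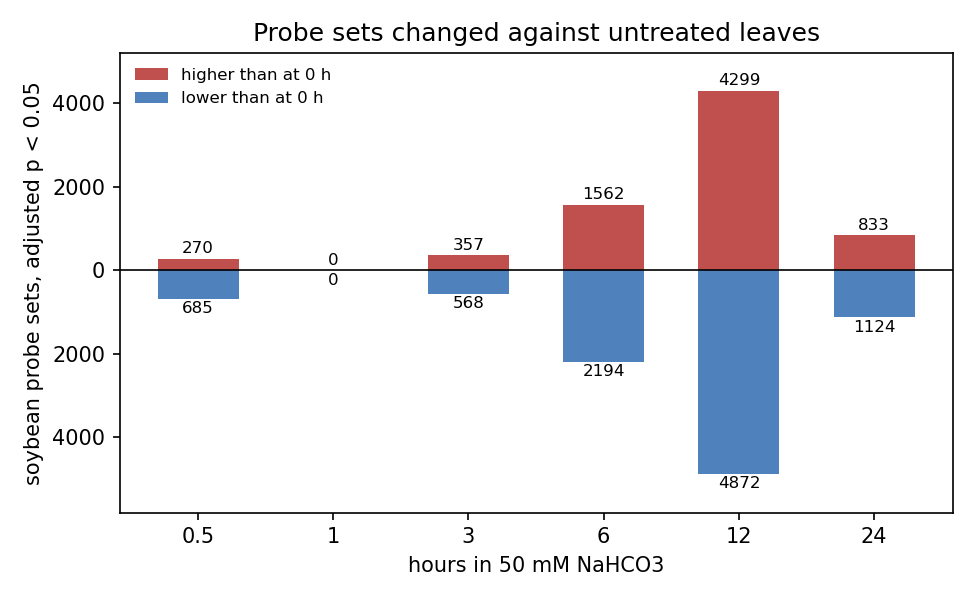
Soybean probe sets called higher (red, above the line) or lower (blue, below the line) than in untreated leaves, against hours in 50 mM sodium bicarbonate. The count was 0 at 1 h and highest at 12 h, with 4299 higher and 4872 lower.

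At 0.5 h the question was which genes respond first. The heat shock factor HSF-03 rose, and the cyclophilin CYP2, the MYB factor MYB183 and the chloroplast gene NDHK, which encodes a subunit of the NADH dehydrogenase-like complex of the thylakoid, fell. So did the calcium-dependent protein kinase CDPK-GAMMA and the calmodulin SCAM-4. Falls were more numerous than rises, and more of them reached 2-fold. HSF-03 rose by 1.37 ± 0.18 (adjusted p = 0.00251) and the gene LOC780539 by 2.02 ± 0.26 (adjusted p = 0.00261). LOC100305762 showed the largest fall of a gene with a symbol, -4.95 ± 0.36 (adjusted p = 0.000166), or 31.0-fold, although its 2 other probe sets did not change. LOC547644 fell by 3.27 ± 0.35, LOC100790389 by 3.22 ± 0.29, CYP2 by 2.34 ± 0.24 (adjusted p = 0.000629) and MYB183 by 1.32 ± 0.15 (adjusted p = 0.00115).

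Smaller or less precise changes at 0.5 h included rises of MYB173 (1.41 ± 0.32), MYB121 (0.93 ± 0.15) and BES1-4 (0.73 ± 0.17), a factor of the brassinosteroid-response family. Falls included NDHK (-2.67 ± 0.44), LBD23 (-1.76 ± 0.29), SCAM-4 (-1.36 ± 0.30), MYB128 (-1.29 ± 0.27), CDPK-GAMMA (-1.23 ± 0.20), GASA27 (-0.88 ± 0.19) and the coproporphyrinogen oxidase CPX (-0.73 ± 0.16), an enzyme of chlorophyll and heme synthesis. PPC1, a phosphoenolpyruvate carboxylase, was at least 1.5-fold lower. Each of these calls ended without 0.5 h replicate 2, and the highest adjusted p without 1 array was 0.0848 (CDPK-GAMMA) to 0.307 (CPX). Of 65 MYB genes, 2 rose and 3 fell, and 4 rose and 3 fell adjusted over the list alone. The median MYB change was 0.13, and without scaling or with quantile normalization 3 rose and 3 fell. Of 16 photosynthesis genes 3 fell (1 with quantile normalization), and of 13 calcium and MAP kinase genes 2 fell (1 without scaling). Of 19 gibberellin and cytokinin genes 1 fell (2 adjusted over the list alone), and 0 with quantile normalization or without scaling. In the heat shock list of 16, 1 gene rose (3 adjusted over the list alone), and 3 of 15 NAC genes rose only when adjusted over the list alone. The kinase SPK-1 (-1.20, adjusted p = 0.082) and the jasmonate enzyme AOC3 (-2.40, adjusted p = 0.138) did not pass the test.

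In the fit of all arrays, 955 probe sets (2.54%) differed at 0.5 h, 270 higher and 685 lower, and 435 of them by at least 2-fold. The share higher was 28.3%, but 44% without scaling of the arrays, 6.21% without 0.5 h replicate 2 and 17.5% without 0 h replicate 2. The count was 145 without 0.5 h replicate 2, 349 without 0.5 h replicate 1, 382 without 0 h replicate 2 and 616 without either 24 h array. Of 22 gene calls chosen by rule, 7 held without each array in turn, those of HSF-03, LOC780539, LOC100305762, LOC547644, LOC100790389, CYP2 and MYB183. The other 15 ended without 0.5 h replicate 2, and 13 also without 0 h replicate 2, 11 without 0.5 h replicate 1, 7 without 0 h replicate 1 and at most 5 without any other array, with adjusted p up to 0.307. The 18S ribosomal RNA signal was lowest at 0.5 h, 44.3 ± 26.5 (SD, n = 2) against 429.9 ± 34.9 at 0 h. Spike-in signals were also lowest of all arrays at 0.5 h, with bioB at 213 and 202 against 484 and 526 at 0 h.

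At 1 h no gene passed the test over all probe sets. HSF-03 (0.85 ± 0.18, adjusted p = 0.224) and MYB121 (0.76 ± 0.15, adjusted p = 0.224) lay above 0, and NIR, the nitrite reductase (-0.88 ± 0.21, adjusted p = 0.268), lay below 0. SPK-1, an SnRK2-type kinase, was not above background at 1 h, at least 2.11-fold below its 0 h mean, and did not pass the test (adjusted p = 0.268). The aquaporin SIP1-3 had the lowest adjusted p of its list, 0.211, at 0.85 ± 0.16. Of 14 pathogenesis and defence genes none passed the test, but their median of -0.32 lay below that of other genes by limma's camera (adjusted p = 0.0172, and adjusted p = 0.849 with an estimated correlation). The list call was also lost without 0 h replicate 1 (adjusted p = 0.261) and without 1 h replicate 1 (adjusted p = 0.117), and the lowest adjusted p over the settings tried was 0.0075. The lowest p in this list was for EDS1-2 (-0.66, adjusted p = 0.378), a regulator of immune signalling. Adjusted over the list alone, 4 of 16 heat shock genes rose, 3 of 65 MYB genes rose and 2 fell, and 1 of 19 aquaporins rose.

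By limma, 0 of 37593 probe sets differed at 1 h. The smallest adjusted p was 0.134, and 3714 probe sets had an unadjusted p under 0.05. The count was 15 without 1 h replicate 1, 8 without 0 h replicate 2, 3 without either 0.5 h array, and 1 without 1 h replicate 2 or without 0 h replicate 1.

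At 3 h the calls were of single genes, and 0 gene lists passed the test. The heat shock factor HSF-08, the small heat shock protein HSP22.3, the chalcone synthase CHS8, which starts flavonoid synthesis, and the DELLA-type growth repressor GAI2 rose. The photoreceptor gene PHYA, the CONSTANS-like gene COL2A, the nitrite reductase NIR and the water channel PIP2-4 fell. HSF-08 rose by 2.33 ± 0.52 (adjusted p = 0.0442), HSP22.3 by 1.29 ± 0.28 (adjusted p = 0.0417), CHS8 by 1.17 ± 0.26 (adjusted p = 0.0426) and GAI2 by 1.07 ± 0.17 (adjusted p = 0.0185). PHYA fell by 0.74 ± 0.13 (adjusted p = 0.0244), COL2A by 0.91 ± 0.18, NIR by 0.96 ± 0.21 and PIP2-4 by 0.99 ± 0.19 (adjusted p = 0.0296). Each of these 8 calls ended without 3 h replicate 1, with adjusted p = 0.0857 (GAI2) to 0.182 (NIR).

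Among genes known by number, LOC100794117 (2.03 ± 0.33) and LOC100810890 (1.59 ± 0.25) rose, and LOC100810608 (-1.59 ± 0.20), LOC100797466 (-1.51 ± 0.26) and LOC100819517 (-1.47 ± 0.26) fell. NRP-B rose by 1.00 ± 0.23 and the glutathione transferase GSTL3 by 0.80 ± 0.18. LBD23 (-1.91 ± 0.29), MYB118 (-1.14 ± 0.24), MYB183 (-1.09 ± 0.15), the receptor-like kinase RLK1 (-1.02 ± 0.17), NAC14 (-0.78 ± 0.15) and the seed maturation gene PM23 (-0.78 ± 0.17) fell. Of these, LOC100810608 held without each array, RLK1 ended without 0 h replicate 2 (adjusted p = 0.0659), and the others ended without 3 h replicate 1, with a highest adjusted p of 0.0659 (MYB183) to 0.216 (NRP-B). Of 65 MYB genes 0 rose and 3 fell, and 3 rose and 6 fell adjusted over the list alone. Of 16 heat shock genes 2 rose (3 adjusted over the list alone). Of 39 phenylpropanoid genes 1 rose, CHS8 (camera adjusted p = 0.309), and of 13 nitrogen genes 1 fell, NIR (camera adjusted p = 0.328). Of 12 light signalling and flowering genes 2 fell, and 1 under quantile normalization. In the NAC list of 15, 1 gene fell while the median was 0.52, and adjusted over the list alone 2 rose and 1 fell. Adjusted over the list alone, 2 of 24 glutathione transferases rose, 1 of 19 aquaporins rose and 3 fell, and 3 of 19 gibberellin and cytokinin genes rose and 1 fell. Over all probe sets those counts were 1 rise, 1 fall and 0 changes. WRKY60 (1.15, adjusted p = 0.069) did not pass the test.

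The count at 3 h was 925 probe sets (2.46%), 357 higher and 568 lower, with 298 at least 2-fold. The share higher was 38.6%, but 59.8% without scaling of the arrays and 64.8% without 3 h replicate 2, so which direction had more calls depends on both. The count was 85 without 3 h replicate 1, 566 without 3 h replicate 2, 158 without 0 h replicate 2, 331 without 0 h replicate 1, 373 without either 24 h array, 441 without either 0.5 h array and 464 without either 6 h array. Of 24 gene calls chosen by rule, only that of LOC100810608 held without each array in turn. Of the others, 22 ended without 3 h replicate 1, 20 without 0 h replicate 2, 13 without 0 h replicate 1, 12 without 3 h replicate 2, and 5 to 10 without each remaining array, with adjusted p up to 0.216.

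At 6 h fatty acid desaturation genes were lower as a list, a call lost with an estimated correlation (adjusted p = 0.609), and transcription factor genes went both ways. The nitrite reductase NIR, the desaturases FAD6.1 and FAD8.2, which make polyunsaturated fatty acids of plastid membranes, and the water channel SIP1-6 were lower. NAC12, MYB127 and the clock gene LUXC, a LUX ARRHYTHMO-like factor of the evening, were higher. NIR fell by 2.49 ± 0.21 (adjusted p = 4.98e-05), FAD6.1 by 2.04 ± 0.15 (adjusted p = 1.95e-05), FAD8.2 fell by 1.31 ± 0.20 (adjusted p = 0.00231) and SIP1-6 by 2.40 ± 0.28 (adjusted p = 0.000405). NAC12 rose by 2.25 ± 0.32 (adjusted p = 0.00134), MYB127 by 2.26 ± 0.31 (adjusted p = 0.00115) and LUXC by 1.99 ± 0.20 (adjusted p = 0.000143).

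The largest rises at 6 h were those of LOC100788166 (4.08 ± 0.31) and LOC100783357 (3.87 ± 0.27). The vacuolar processing enzyme VPE2 (2.98 ± 0.60), a protease of the vacuole, and WRKY43 (2.45 ± 0.43) followed among genes with a name, although both calls ended without 6 h replicate 1 (adjusted p = 0.0933 and 0.0515). Of the falls, LOC100779717 was at least 19.0-fold lower and LOC100797466 at least 14.4-fold lower, while LOC100795628 fell by 4.29 ± 0.19 and MYB118 by 3.83 ± 0.24 (adjusted p = 7.42e-06). LBD23 (-2.76 ± 0.29), the matrix metalloproteinase MMP2 (-2.69 ± 0.33) and MYB138 (-2.65 ± 0.41) also fell. Sugar transporters of the SWEET family went both ways: SWEET34 fell by 2.38 ± 0.22, SWEET29 was at least 4.4-fold lower and SWEET31 at least 2.29-fold higher.

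By group, 5 of 16 desaturation and membrane lipid genes fell at 6 h and 0 rose, with a median of -0.77 (camera adjusted p = 0.0035, and adjusted p = 0.609 with an estimated correlation). Of 13 nitrogen genes 4 fell (camera adjusted p = 0.236), among them the nitrate reductase INR2 (-1.58 ± 0.35). Of 19 aquaporins 5 fell and 0 rose (camera adjusted p = 0.142), and 5 fell and 3 rose adjusted over the list alone; without scaling of the arrays 1 rose. Examples are SIP1-6 and NIP2-2, which was at least 2.35-fold lower. Of 16 photosynthesis genes 4 fell, or 2 with quantile normalization, with CHLH, a subunit of the magnesium chelatase of chlorophyll synthesis, at -0.72 ± 0.13. Of 16 heat shock genes 3 fell (1 rose and 3 fell adjusted over the list alone), with HSP23.9 at -2.39 ± 0.42. Of 39 phenylpropanoid genes, 2 rose and 4 fell. The isoflavone reductase IFR2 rose by 1.78 ± 0.31 and the anthocyanidin synthase ANS2 by 1.25 ± 0.24, and 4CL4 fell by 1.37 ± 0.25. The call of 4CL4 ended without 6 h replicate 1 (adjusted p = 0.0533), and those of INR2 (0.116) and ANS2 (0.0738) ended without 6 h replicate 2. Both glutathione transferases called, of 24, rose: GSTL3 by 1.21 ± 0.18 and GSTU28 by 1.00 ± 0.13. This list's median was -0.14, and 2 rose adjusted over the list alone.

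Among transcription factors at 6 h, 5 of 52 WRKY genes rose and 1 fell (6 and 1 adjusted over the list alone), and 3 of 15 NAC genes rose and 1 fell, as adjusted over the list alone, with 0 falls under quantile normalization. Of 65 MYB genes, 6 rose and 12 fell (10 and 14 adjusted over the list alone). Of 59 bZIP genes, 2 rose and 3 fell (the same counts adjusted over the list alone), but with quantile normalization or without scaling 3 rose and 2 fell. Over all soybean probe sets 9.99% were called at 6 h, and the WRKY and bZIP counts lie near that share. WRKY60 rose by 1.5 ± 0.30 and NAC34 by 1.98 ± 0.40, BZIP46 fell by 1.45 ± 0.26 and BZIP36 was at least 3.12-fold lower. Of 7 genes in the list of SnRK2 kinases and abscisic acid, 1 rose, SPK-4, by 0.50 ± 0.13 (adjusted p = 0.0331). The calls of WRKY60 (adjusted p = 0.0881) and NAC34 (0.0889) ended without 6 h replicate 1, and that of SPK-4 (0.151) without 6 h replicate 2. Of 19 gibberellin and cytokinin genes 2 rose and 1 fell (3 and 1 adjusted over the list alone) with a median of -0.07: GASA32, a GASA-type peptide gene, rose by 1.79 ± 0.30 and GASA22 fell by 1.38 ± 0.15. The 12 jasmonate genes gave 0 changes over all probe sets and adjusted over the list alone.

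At 6 h 3756 probe sets (9.99%) differed, 1562 higher and 2194 lower, with 1584 at least 2-fold. The share higher was 41.6%, and 52.5% without scaling. The count was 1489 without 6 h replicate 1, 1541 without 6 h replicate 2 and 2453 without 0 h replicate 1. Of 78 gene calls chosen by rule, 39 held without each array in turn. Without 6 h replicate 1, 28 ended, and 26 without 6 h replicate 2, 20 without 0 h replicate 1, 17 without 0 h replicate 2 and at most 10 without any other array, with adjusted p up to 0.311. The 18S ribosomal RNA signal was highest at 6 h, 1985 ± 409 (SD, n = 2).

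At 12 h heat shock genes were higher as a list, and genes of photosynthesis and chlorophyll synthesis were lower as a list. Both list calls were lost with an estimated correlation (adjusted p = 0.849 for each). HSP90A1, a cytosolic chaperone, rose by 4.77 ± 0.26 (27.3-fold, adjusted p = 8.27e-07), and HSP22.3 by 2.83 ± 0.28 (adjusted p = 5.33e-05). MYB134 fell by 5.32 ± 0.15 (40-fold, adjusted p = 1.69e-08), and the morning clock gene LHY by 3.98 ± 0.28 (15.8-fold, adjusted p = 4.24e-06). FAD6.1 fell by 3.28 ± 0.15 (adjusted p = 3.13e-07), and CHLH by 2.25 ± 0.13 (adjusted p = 1.16e-06). SBPRP, a proline-rich protein gene, fell by 4.21 ± 0.28.

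Further rises at 12 h were those of LOC100788166 (3.98 ± 0.31), LOC100803175 (3.58 ± 0.40), VPE2 (3.12 ± 0.60, adjusted p = 0.00355) and ERD15 (2.74 ± 0.60, adjusted p = 0.00765), named for early response to dehydration. The call of ERD15 ended without 12 h replicate 1 (adjusted p = 0.0572). LOC100500220 was at least 15.3-fold higher. LOC100779717 was at least 21.5-fold lower, and LOC100500586 (-4.60 ± 0.19), MYB118 (-3.80 ± 0.24) and MYB114 (-3.76 ± 0.24) fell. SCA1, a calcium-transporting ATPase, fell by 3.10 ± 0.44 and SCAM-4 by 1.78 ± 0.30, while of 13 calcium and MAP kinase genes 2 rose and 2 fell (camera adjusted p = 0.937). The CONSTANS-like gene COL10 fell by 3.01 ± 0.21, the ammonium transporter AMT1.3 fell by 2.51 ± 0.24 and the sucrose transporter SUT1 by 1.62 ± 0.29.

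Of 16 heat shock genes, 9 rose at 12 h and 0 fell, as adjusted over the list alone. The median was 0.97 (camera adjusted p = 0.0035, and adjusted p = 0.849 with an estimated correlation). Of 16 photosynthesis genes, 10 fell and 1 rose, with a median of -0.73 (camera adjusted p = 0.0132, and adjusted p = 0.849 with an estimated correlation). The NADH dehydrogenase-like subunit NDHK fell by 2.70 ± 0.44, and the gene that rose was PETC, the Rieske protein of the cytochrome b6f complex, by 0.41 ± 0.13. Of 16 desaturation genes, 6 fell and 1 rose, with FAD8.2 at -2.04 ± 0.20 (camera adjusted p = 0.0511). Of 39 phenylpropanoid genes 13 fell and 0 rose, and 10 fell under quantile normalization or without scaling (camera adjusted p = 0.125). The isoflavone glucosyltransferase IF7GT fell by 1.98 ± 0.36 and CYP98A2, a cytochrome P450 of lignin synthesis, by 1.53 ± 0.21. Aquaporins gave 8 falls and 1 rise of 19 (9 and 1 adjusted over the list alone), with SIP1-6 at -2.56 ± 0.28 and PIP2-1 at -2.18 ± 0.35. Glutathione transferases gave 7 rises and 3 falls of 24 (9 and 4 adjusted over the list alone), with GSTU62 at 1.57 ± 0.38 and GSTU47 at -1.91 ± 0.44. The call of PETC ended without 12 h replicate 2 (adjusted p = 0.108), that of GSTU62 without 12 h replicate 1 (0.104) and that of GSTU47 without 0 h replicate 1 (0.0652).

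Genes in the list of SnRK2 kinases and abscisic acid went both ways at 12 h. Of the 7 genes, 2 rose and 1 fell, and without scaling 3 rose and 1 fell. The SnRK2-type kinase genes SPK-2 (1.26 ± 0.21, adjusted p = 0.00166) and SPK-4 (0.76 ± 0.13, adjusted p = 0.0018) rose. ZEP, zeaxanthin epoxidase, which acts early in abscisic acid synthesis, fell by 1.36 ± 0.24 (adjusted p = 0.00198). Among transcription factors, 10 of 65 MYB genes rose and 22 fell (12 and 22 adjusted over the list alone), with MYB127 at 2.33 ± 0.31 and MYB177 at 2.32 ± 0.30. Of 59 bZIP genes 6 rose and 10 fell, as adjusted over the list alone, but without scaling 6 rose and 6 fell. BZIP50 fell by 1.80 ± 0.32, BZIP46 by 1.79 ± 0.26, and BZIP109 rose by 0.86 ± 0.14. Of 15 NAC genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), with NAC12 at 1.98 ± 0.32 and NAC51 at 1.43 ± 0.24. Of 52 WRKY genes 1 rose, WRKY9 at 1.14 ± 0.29, and 2 fell, as adjusted over the list alone, and with quantile normalization or without scaling 2 rose and 2 fell. Of 19 gibberellin and cytokinin genes 4 rose and 2 fell, as adjusted over the list alone, with GASA22 at 1.95 ± 0.15. Of 12 jasmonate genes 1 fell, the allene oxide synthase AOS2 (-1.85 ± 0.58), and 0 adjusted over the list alone. The call of WRKY9 ended without 12 h replicate 1 (adjusted p = 0.126), and that of AOS2 without 12 h replicate 2 (0.192).

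In all, 9171 probe sets (24.4%) differed at 12 h, 4299 higher and 4872 lower, with 3159 at least 2-fold. The share higher was 46.9%, and 53.6% with quantile normalization and 55.6% without scaling, so which direction had more calls depends on the scaling. On the 12 h arrays the ratio of the 3′ to the middle GAPDH control probe sets was 0.644 and 0.507, against 0.886 to 1.39 on the others, while the 3′ to 5′ actin ratios of 3.74 and 3.85 lay within the 2.88 to 5.72 of the others. The count was 5622 without 12 h replicate 1 and within 1.5 times without any other array. Of 98 gene calls chosen by rule, 55 held without each array in turn. Without 12 h replicate 1, 35 ended, and 28 without 0 h replicate 2, 22 without 12 h replicate 2, 17 without 0 h replicate 1 and at most 6 without any other array, with adjusted p up to 0.330.

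**Figure D2:**
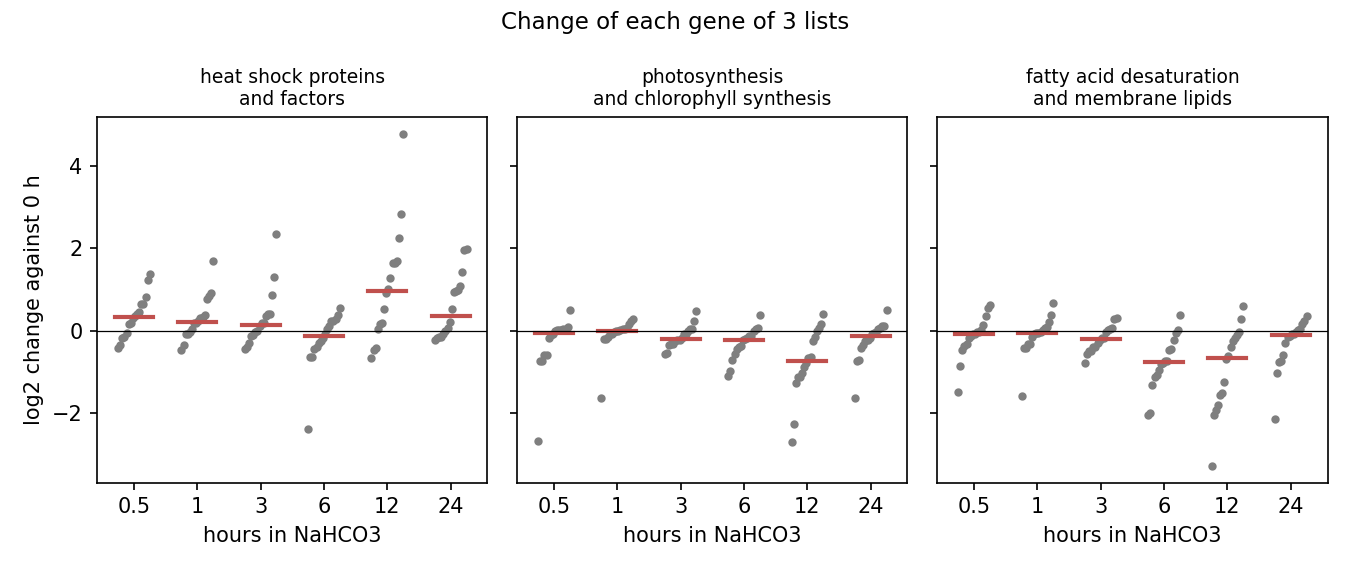
Log2 change against 0 h of each gene (grey dots) in 3 lists, against hours in sodium bicarbonate, with the list's median as a red bar. The heat shock median was 0.97 at 12 h, the photosynthesis median -0.73 at 12 h and the desaturation median -0.77 at 6 h.

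At 24 h, the clock hour of the untreated leaves, heat shock genes were higher as a list, and the other calls were of single genes. The list call was lost with an estimated correlation (adjusted p = 0.849) and without 0 h replicate 2 (adjusted p = 0.164). HSF-03 rose by 1.98 ± 0.18 (adjusted p = 0.00143), MYB121 by 1.48 ± 0.15 (adjusted p = 0.00225) and HSP90A1 by 1.95 ± 0.26 (adjusted p = 0.00583). The Kunitz trypsin inhibitor genes KTI-3 (1.27 ± 0.23) and KTI-2 (1.22 ± 0.26), the chalcone synthase CHS8 (1.12 ± 0.26) and the anthocyanidin synthase ANS2 (1.1 ± 0.24) rose as well. SCA1 fell by 2.06 ± 0.44, BZIP50 by 1.68 ± 0.32, SCAM-4 by 1.44 ± 0.30 and the water channel PIP1-6 by 1.37 ± 0.27. HSF-03 and MYB121 held without each array, and the other 9 calls ended without 24 h replicate 1, with a highest adjusted p of 0.064 (HSP90A1) to 0.21 (CHS8).

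The 5 largest rises at 24 h were of genes known by number. LOC100306340 was at least 5.26-fold higher and LOC100306414 at least 5.14-fold higher, LOC100808125 rose by 2.52 ± 0.49, and LOC547822 fell by 2.69 ± 0.35 and LOC100306079 by 2.02 ± 0.19 (adjusted p = 0.00143). LOC100803175, higher at 12 h, was at least 2.96-fold lower. MYB173 (2.13 ± 0.32), GASA24 (1.94 ± 0.41), NAC12 (1.65 ± 0.32), the superoxide dismutase SOD1 (1.06 ± 0.26) and the P450 gene CYP83E8 (0.94 ± 0.14) rose. GASA6 was at least 3.53-fold lower, and LBD23 (-1.72 ± 0.29), AKR1 (-1.64 ± 0.36), BZIP46 (-1.25 ± 0.26), NIR (-0.85 ± 0.21) and CPX (-0.71 ± 0.16) fell. LOC100306079 held without each array, LOC100306414 ended without 24 h replicate 2 (adjusted p = 0.103), and the others ended without 24 h replicate 1, with a highest adjusted p of 0.0593 (LOC547822) to 0.221 (NIR).

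Of 16 heat shock genes 5 rose at 24 h and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.0132, and adjusted p = 0.849 with an estimated correlation). Of 39 phenylpropanoid genes 2 rose (camera adjusted p = 0.15), of 16 seed storage and protease inhibitor genes 2 rose (0.729), and of 13 calcium and MAP kinase genes 2 fell (0.284). In each of the 5 list calls of the course, the median, the mean and the test had the same sign. Of 65 MYB genes 7 rose and 1 fell (8 and 1 adjusted over the list alone). Of 59 bZIP genes 0 rose and 4 fell, and 4 rose and 5 fell adjusted over the list alone, while without scaling 3 rose and 4 fell. Of 52 WRKY genes 2 rose and 1 fell (3 and 1 adjusted over the list alone, 3 and 0 without scaling). Of 15 NAC genes 2 rose and 0 fell (4 and 0 adjusted over the list alone, 1 and 0 with median centring). Gibberellin and cytokinin genes gave 1 rise and 2 falls of 19 (1 and 4 adjusted over the list alone), and 1 of each with quantile normalization or without scaling. Aquaporins gave 1 fall and 0 rises of 19 (3 falls and 1 rise adjusted over the list alone) with a median of 0.00335, and 1 of each with quantile normalization or without scaling. In the list of SnRK2 kinases and abscisic acid 0 of 7 changed (1 rose and 2 fell adjusted over the list alone). In the jasmonate list 0 of 12 changed (1 rose and 2 fell adjusted over the list alone). The allene oxide cyclase AOC4, not above background at 24 h, was at least 4.85-fold below its 0 h mean and did not pass the test (adjusted p = 0.0658).

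At 24 h 1957 probe sets (5.21%) differed, 833 higher and 1124 lower, with 636 at least 2-fold. The share higher was 42.6%, and 57.2% without scaling. The count was 34 without 24 h replicate 1, 91 without 24 h replicate 2, 450 without 0 h replicate 2, 1249 without either 0.5 h array and 1282 without either 6 h array. Of 40 gene calls chosen by rule, 3 held without each array in turn, those of HSF-03, MYB121 and LOC100306079. Of the others, 36 ended without 24 h replicate 1, 33 without 24 h replicate 2, 31 without 0 h replicate 2, 18 without 0 h replicate 1 and at most 8 without any other array, with adjusted p up to 0.234. The heat shock list call was lost without 0 h replicate 2 (adjusted p = 0.164), the highest of a range from 0.00108 over the settings other than an estimated correlation.

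The clock genes were followed because light and dark alternated every 12 h. LHY and LCL3, an LHY-like gene, were low at 12 h and high again at 24 h, and LUXC did the opposite. LCL3 was at least 4.06-fold lower and LUXC higher by 2.45 ± 0.20 at 12 h than at 0 h. Between 12 and 24 h LHY rose by 4.53 ± 0.28 (adjusted p = 1.59e-06), LCL3, not above background at 12 h, was at least 9.1-fold higher (adjusted p = 3.18e-06), and LUXC fell by 2.85 ± 0.20 (adjusted p = 3.57e-06). ZTL1, an F-box protein of the clock, differed by 0.06 ± 0.17 (adjusted p = 0.87). Relative to 0 h, the 24 h values were 0.54 for LHY (adjusted p = 0.274), -0.40 for LUXC (adjusted p = 0.256) and 1.16 ± 0.23 for LCL3, which rose (adjusted p = 0.0235, but 0.147 without 24 h replicate 1). At 6 h LCL3 (-1.63 ± 0.23) and LHY (-1.29 ± 0.28) had already fallen, LHY with adjusted p = 0.0948 without 6 h replicate 1. None of the 4 passed the test at 0.5, 1 or 3 h, where the values of LHY were 0.22, 0.05 and -0.10 and those of LCL3 0.80, 0.16 and 0.24.

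**Figure D3:**
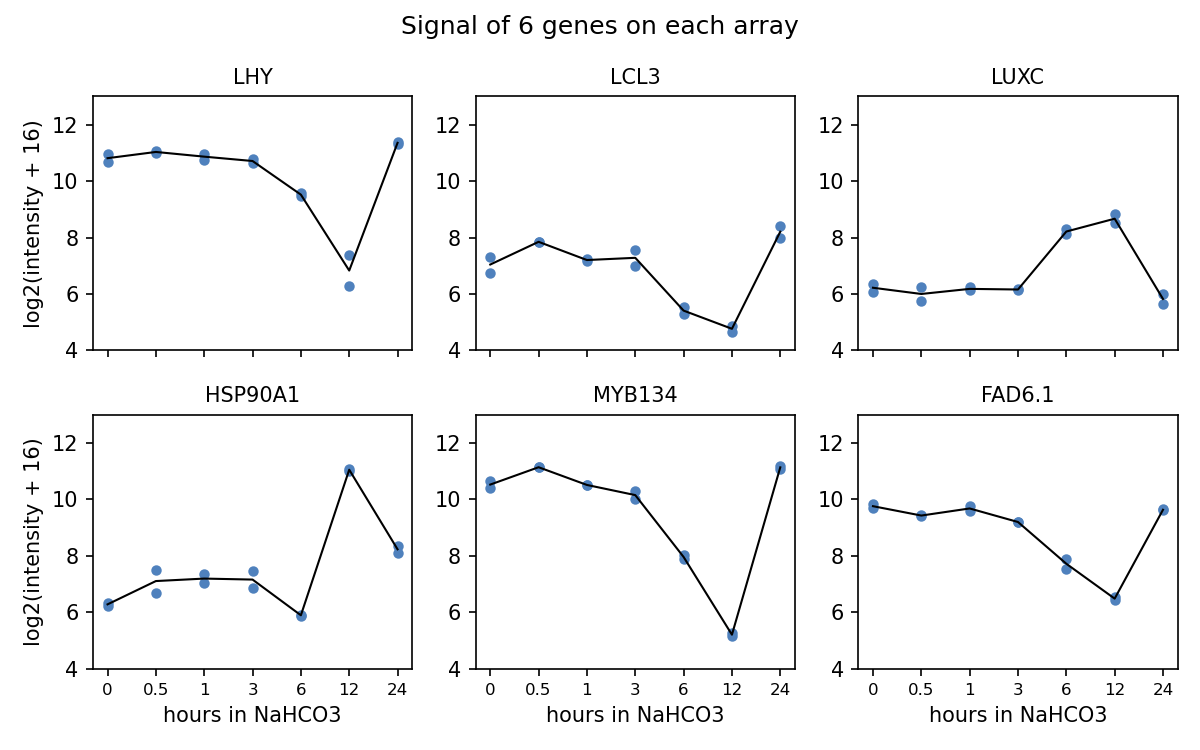
Signal of 6 genes, as log2 of the scaled intensity plus 16, against hours in sodium bicarbonate at evenly spaced positions, with a dot for each array and a line through the means. LHY, LCL3, MYB134 and FAD6.1 are lowest at 12 h, where LUXC and HSP90A1 are highest.

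Between consecutive times the largest turnover was from 12 to 24 h, with 5693 probe sets changed, 3048 higher and 2645 lower. The steps differ in length and that step is the longest, so the counts are not rates. MYB134 rose by 5.93 in that step, and MYB114, above background on 1 of the 12 h arrays, by 4.83. From 6 to 12 h 3575 changed (1554 higher, 2021 lower), among them HSP23.9, which rose by 4.07, and MYB177, which was at least 12.7-fold higher. From 3 to 6 h 1868 changed (764 higher, 1104 lower), from 1 to 3 h 897 (464 higher, 433 lower) and from 0.5 to 1 h 1410 (896 higher, 514 lower). With quantile normalization the share higher was 49.9% in place of 53.5% from 12 to 24 h. Without scaling the share higher was 40.2% in place of 63.5% from 0.5 to 1 h and 74.1% in place of 51.7% from 1 to 3 h. It was 47.4% from 1 to 3 h without either 0 h array, and 26.1% in place of 40.9% from 3 to 6 h without 3 h replicate 2. From 12 to 24 h the count was 3137 without 12 h replicate 1, 2791 without 24 h replicate 1 and 2944 without 24 h replicate 2. From 6 to 12 h it was 1372 and 1195 without 6 h replicate 1 or 2 and 1601 without 12 h replicate 1. From 3 to 6 h it was 913 without 3 h replicate 1, and 760 and 372 without 6 h replicate 1 or 2. From 1 to 3 h it was 158 and 29 without 1 h replicate 1 or 2, 123 without 3 h replicate 1, 523, 549 and 444 without an array of 0.5, 6 or 24 h. From 0.5 to 1 h it was 491 and 76 without 0.5 h replicate 1 or 2, 519 and 128 without 1 h replicate 1 or 2, 2483 without either 0 h array, 824 without either 6 h array and 700 without either 24 h array.

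Changes at 6 and 12 h overlapped. NAC12, MYB127, LUXC, LOC100788166, the cyclophilin CYP26 and the 14-3-3 protein gene GF14B rose at both times, and MYB118, FAD6.1, SIP1-6, COL2A, PM23 and LOC100779717 fell at both. Of the probe sets called at both, 949 were higher at both, 1622 lower at both and 51 opposite, where independent lists of those sizes would share 179, 284 and 453. Between 12 and 24 h, 415 were higher at both, 738 lower at both and 118 opposite, against 95.3, 146 and 236 for independent lists. Between 0.5 and 24 h, 116 were higher at both and 240 lower at both, with 0 opposite, against 5.98, 20.5 and 23.3. Opposite calls were more frequent between 6 and 24 h, with 176 higher at both, 246 lower at both and 153 opposite, against 34.6, 65.6 and 95.3. Between 0.5 and 6 h, 58 were higher at both, 167 lower at both and 47 opposite, against 11.2, 40 and 44.2. Across probe sets, which are not independent replicates, the changes correlated at 0.66 for 6 and 12 h, 0.43 for 12 and 24 h, 0.64 for 0.5 and 24 h, 0.292 for 6 and 24 h and 0.325 for 0.5 and 6 h. Simulated unchanged groups against the same 0 h arrays gave about 0.5 for each pair. The covariance was above the simulated one by 0.191, 0.0906, 0.0823, 0.0358 and 0.0402. The same 0 h arrays served every comparison, so part of the shared calls may come from them.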

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

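The test of the 24 h changes against time of day was chosen only after the results were seen. So was that of the 0.5 h falls against ribosomal RNA by the change from 1 to 6 h. The spike-in values were compared without a test. The other tests of an explanation here were fixed before their results. The changes of ribosomal RNA and of the other organisms' probe sets lie outside the soybean contrasts that were fixed before. The named genes that went in opposite directions were picked from calls already made.

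The changes at 12 h were compared with those at 24 h, because 12 h lies at the other end of the day from the untreated leaves and 24 h does not. If time of day alone made the 12 h changes, they would vanish by 24 h: the median share of the 12 h change still present at 24 h was 0.363 over 9171 probe sets (quartiles 0.0581 and 0.648), with 40.4% of shares under 0.25 and 37.7% above 0.5. Taking a different 0 h array for each time gave 0.359 and 0.345. The probe sets were still chosen with both 0 h arrays, so this does not remove the effect of sharing them. Time of day and treatment cannot be told apart for the 12 h changes, because no untreated leaves of that hour were analysed here and the share lies between the bounds set for either. At 24 h, where the clock hour is that of 0 h, 1957 probe sets differed (34 and 91 without 24 h replicate 1 or 2, 450 without 0 h replicate 2, 1249 without either 0.5 h array and 1282 without either 6 h array), all above the 8 false calls of the simulation, but a simulated bound does not exclude time of day and LCL3, a clock gene, was itself higher at 24 h (1.16, a call lost at 0.88 without 0 h replicate 2 and at 0.95 and 1.38 without 24 h replicate 1 or 2).

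The changes at 0.5 h differed from those at 1 h: 1410 probe sets differed between the 2 times, but 491 and 76 without 0.5 h replicate 1 or 2, 519 and 128 without 1 h replicate 1 or 2, 2483 without either 0 h array, 824 without either 6 h array and 700 without either 24 h array. The scaling done here is argued against as the cause of most 0.5 h calls. After quantile normalization 88.9% of them kept their call and direction, and without scaling 84.1%. The split did depend on scaling: without it 419 were higher and 533 lower at 0.5 h, in place of 270 and 685. Scaling before deposit cannot be tested with these values. Whether less ribosomal RNA in the 0.5 h targets made the falls is not decided. The test used the change from 1 to 6 h. Over it the 18S signal rose by 3.67, more than the 3.02 by which it was lower at 0.5 h. The 685 probe sets that fell at 0.5 h regained a median share of -0.116 of their fall (quartiles -0.416 and 0.212, and medians of -0.196 to -0.0595 over the pairs of a 6 h and a 1 h array). As a set they did not follow 18S over that span. However, their median change had already gone from -1.02 at 0.5 h to -0.23 at 1 h, where 18S was still lower by 1.59. At 1 h 388 of them were higher than at 0.5 h past the test. Little of the fall was thus left to regain, and treatment and time of day also changed by 6 h. Their correlations with 18S over the arrays of 1 to 24 h, the test fixed before, went both ways (median -0.107, permutation p = 0.607). A difference in hybridisation or scanning cannot be told apart from treatment. On the other organisms' probe sets the 0.5 h arrays correlated at -0.0713 with the 24 h arrays and at -0.111 with the 0 h and 1 h arrays. The difference of 0.0398 lay between the bounds of 0 and 0.05 set for it. The correlation was higher with the 12 h (-0.00996) and 3 h (-0.0346) arrays, so the 24 h arrays were not the most alike. With the 6 h arrays it was -0.109, and none of these values was above 0. The spike-in signals of the 0.5 h arrays were the lowest of all arrays. At 0.5 h bioB was 213 and 202 against 484 and 526 at 0 h, and bioD 2080 and 1767 against 3677 and 3857.

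The 18S ribosomal RNA, which is outside the soybean tests, was higher at 6 h than in the untreated leaves by 2.08 on the log2 scale (SE 0.277, adjusted p = 0.000838), with an intensity of 1985 against 429.9. Carry-over of ribosomal RNA into the labelled target may account for it, and a real change in ribosomal RNA would show the same values: the 23 of 24 sense ribosomal probe sets above background followed the 18S signal over the 14 arrays, with a median r of 0.954 (range 0.675 to 0.981, rho 0.886, permutation p = 1e-05, the smallest the permutations can give, and r = 0.937 without the 2 farthest arrays). The scaling done here is argued against, since the difference in its scale factors was 0.0359 of the log2 difference in 18S signal. The deposited values already look scaled to one another, so scaling before deposit cannot be tested this way. The test does not separate carry-over from a change in the leaves, and no biological explanation was tested.

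The number of probe sets that changed from 1 time to the next was 1410 from 0.5 to 1 h, 897 from 1 to 3 h and 1868 from 3 to 6 h. It was 3575 from 6 to 12 h and 5693 from 12 to 24 h. Each is a tested difference between 2 times, and the steps differ in length. Leaving out 1 array moved the first as given above, to as few as 76 without 0.5 h replicate 2. From 1 to 3 h it gave 158 and 29 without 1 h replicate 1 or 2, 123 without 3 h replicate 1, 523 without either 0.5 h array, 549 without either 6 h array and 444 without either 24 h array. From 3 to 6 h it gave 913 without 3 h replicate 1, and 760 and 372 without 6 h replicate 1 or 2. From 6 to 12 h it gave 1372 and 1195 without 6 h replicate 1 or 2, and 1601 without 12 h replicate 1. From 12 to 24 h it gave 3137 without 12 h replicate 1, and 2791 and 2944 without 24 h replicate 1 or 2. Clock genes differed between 12 and 24 h by 4.53 for LHY, 3.44 for LCL3 and -2.85 for LUXC. The 3.44 is a fitted value for a gene not above background at 12 h, where only at least 9.1-fold can be said. LCL3 differed between 6 and 24 h by 2.80.

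Some named genes passed the test against 0 h in opposite directions at 2 times. Since they were chosen for that, the differences below are no separate evidence. LOC100790389 was higher at 6 than at 0.5 h by 4.99 and GASA27 higher at 12 than at 0.5 h by 1.66. NAC14 was higher at 12 h than at 3 h by 1.69 and than at 6 h by 1.52. From 6 to 12 h HSP23.9 differed by 4.07, GASA22 by 3.33 and MYB177 by a fitted 4.37 (at least 12.7-fold, not above background at 6 h), and from 12 to 24 h GASA22 by -2.59. From 6 and from 12 h to 24 h, MYB134 differed by 3.18 and 5.93, and MYB114 by 3.01 and 4.83, the latter with 1 of the 12 h arrays above background. LOC100803175, not above background at 24 h, had fitted differences of -4.88 and -5.73, or at least 19.6-fold and 35.3-fold lower. LOC100779717, not above background at 6 and 12 h, had fitted differences of 5.46 and 5.91, or at least 33.2-fold and 37.6-fold higher.

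Probe sets of the 2 other organisms, which serve as background, also gave calls above the untreated leaves: 2 at 0.5 h, 5 at 1 h, 9 at 3 h, 13 at 6 h, 30 at 12 h and 14 at 24 h, of 23350. The calls below the untreated leaves numbered 78, 4, 20, 33, 398 and 77 at the same times. Their median change was lowest at 0.5 h (-0.141) and 12 h (-0.134), and -0.0932 at 6 h. With the filter on dim probe sets, 340 soybean probe sets were higher and 715 lower at 0.5 h, and 4348 and 4715 at 12 h. Whether this lower signal added to the soybean falls was not tested.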

How the results depend on the processing

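The alternatives without scaling, without the 12 h arrays and without the 0.5 h arrays were chosen only after the results were seen; the others were fixed before. Each group has 2 arrays, so leaving out 1 leaves a lone array that is assumed to vary like the other groups. A signal under background cannot show a fall, and a gene near it gives only a bound. Of 262 calls of named genes, 95 held under every setting, 167 were lost under at least 1 and 0 changed sign. A fit without a time gives no value for that time, and the fit of only the groups compared gives no F test over the course. Where a setting's construction is not named as the cause, the cause was not tested.

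Stricter thresholds leave fewer calls by construction. With at least 2-fold, 435 probe sets remained at 0.5 h, 298 at 3 h, 1584 at 6 h, 3159 at 12 h and 636 at 24 h. With adjusted p under 0.01 in place of 0.05, 230, 5, 1444, 4455 and 123 remained at those times, against 955, 925, 3756, 9171 and 1957 called in the full fit.

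The count of gene lists past the test, which was 0, 1, 0, 1, 2 and 1 at 0.5, 1, 3, 6, 12 and 24 h, was 3, 4, 7, 5, 6 and 5 with all probe sets of a gene, where genes with several probe sets count more than once. It was 0 at 1 h, 0 at 6 h, 0 at 12 h and 0 at 24 h with an estimated inter-gene correlation. At 1 h it was 3 with median centring, 2 with the filter on dim probe sets, 4 with log2(value + 1), 2 with trend and robust eBayes settings, 2 without scaling, 5 with only the groups compared and 4 without the 0.5 h arrays. At 3 h it was 1 with median centring, 2 with log2(value + 1), 1 with trend and robust settings, 3 with only the groups compared and 2 without the 0.5 h arrays. With the filter on dim probe sets it was 2 at 0.5 h, 3 at 12 h and 2 at 24 h. At 12 h it was also 3 with quantile normalization, median centring, log2(value + 1), the replicate block and trend and robust settings. Values without scaling and the fit without the 0.5 h arrays gave 3 at 12 h too. It stayed at 2 there with log2(value + 64) and with the array's other probe sets included. With only the groups compared it was 1 at 0.5 h, 2 at 6 h, 4 at 12 h and 3 at 24 h.

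With only the groups compared, the spread rests on 4 arrays. The count was 175 at 0.5 h, 0 at 3 h by limma, 1714 at 6 h, 3642 at 12 h and 236 at 24 h. Between consecutive times it was 267 from 0.5 to 1 h, 0 from 1 to 3 h by limma, 682 from 3 to 6 h and 1919 from 6 to 12 h. From 12 to 24 h it was 4599, against 5693 in the full fit. The drops thus differed between comparisons that each rest on 4 arrays, and their cause was not tested.

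With log2(value + 1), which gives dim probe sets more spread, the count was 620 at 0.5 h, 51 at 3 h, 950 at 24 h, 598 from 0.5 to 1 h, 256 from 1 to 3 h and 1158 from 3 to 6 h. With log2(value + 64) it was 1614 at 3 h and 1409 from 1 to 3 h. With all 61170 probe sets of the array included, among them those of other organisms and the 227 control and ribosomal RNA ones, it was 50 at 1 h. That count is over all of these probe sets, not soybean alone. Without the 0.5 h arrays it was 3 at 1 h, 441 at 3 h, 1249 at 24 h and 523 from 1 to 3 h. Without the 12 h arrays and with quantile normalization no count of probe sets at a time moved by over 1.5 times, and 88.9, 80.3, 92.5, 93.3 and 90.9% of the calls at 0.5, 3, 6, 12 and 24 h held their direction with quantile normalization.

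With the replicate number as a block, 2 probe sets differed at 1 h and 569 at 3 h, and 3 lists at 1 h and 1 list at 3 h passed the test. Same-numbered replicates do not pair the samples: over 21 pairs of times the deviations from the group mean correlated at -0.219 to 0.226, with a median of -0.0524. The block was therefore not used for the results.

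With each array left out in turn, the count ranged from 145 to 1258 at 0.5 h, 0 to 15 at 1 h, 85 to 822 at 3 h, 1489 to 3797 at 6 h, 5622 to 9111 at 12 h and 34 to 2029 at 24 h. Between consecutive times it ranged from 76 to 2483 (0.5 to 1 h), 29 to 1288 (1 to 3 h), 372 to 2199 (3 to 6 h), 1195 to 4074 (6 to 12 h) and 2791 to 6363 (12 to 24 h). Lists past the test ranged from 0 to 3 at 0.5 h, 0 to 5 at 1 h, 0 to 4 at 3 h, 1 to 2 at 6 h and 0 to 2 at 24 h.

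Clock genes that did not pass the test changed sign over the arrays left out. At 0.5 h, LUXC ranged from -0.469 without 0.5 h replicate 2 to 0.0289 without 0.5 h replicate 1, and ZTL1 from -0.141 without 0 h replicate 2 to 0.173 without 0 h replicate 1. At 1 h the lowest values came without 0 h replicate 2 and the highest without 0 h replicate 1: -0.125 to 0.442 for LCL3, -0.0912 to 0.20 for LHY, -0.184 to 0.104 for LUXC and -0.183 to 0.131 for ZTL1. At 3 h the same arrays gave -0.245 to 0.0457 for LHY and -0.206 to 0.0823 for LUXC, and LCL3 ranged from -0.046 without 3 h replicate 2 to 0.522 without 3 h replicate 1. Between 12 and 24 h ZTL1 ranged from -0.146 without 12 h replicate 2 to 0.262 without 12 h replicate 1. Without scaling LUXC was 0.0053 at 3 h. The cause was not tested.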

Other observations

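Single genes of phosphate and sulfur supply fell at 6 or 12 h, while neither list passed the test. The phosphate-response factor PHR was at least 3.74-fold lower at 6 h and fell by 1.54 ± 0.17 at 12 h (adjusted p = 0.000108), and CGS2, of methionine synthesis, fell by 0.99 ± 0.12 at 12 h (adjusted p = 0.000219). Of 19 phosphate genes 1 rose and 4 fell at 12 h (camera adjusted p = 0.77, and 0.138 at 6 h), and of 10 sulfur genes 1 rose and 3 fell (0.399, and 0.309 at 6 h). The kinase WNK13 fell by 1.36 ± 0.22 at 6 h and 1.3 ± 0.22 at 12 h, and the seed maturation gene PM23 by 2.43 ± 0.17 at 12 h. GF14B rose by 1.00 ± 0.16 at 6 h and 1.12 ± 0.16 at 12 h, CYP26 by 1.02 ± 0.14 and 1.43 ± 0.14, and MAPK2 by 0.68 ± 0.12 at 12 h. Of 10 glyoxalase genes 2 rose at 12 h, GLYII-6 by 1.16 ± 0.22 and GLYII-5 by 0.77 ± 0.14, and 1 fell, GLYI-23, by 0.94 ± 0.20. These calls held without each array in turn. The 10 vegetative storage and lipoxygenase genes gave 0 changes.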
